A study of Mus musculus with 4 samples.

How the data were processed

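Expression was measured with 4 Affymetrix mouse arrays of 22690 probe sets, 1 each for macrophages from remodeling mammary glands and from early-stage PyMT mammary tumors, labelled Ets2-expressing or Ets2-deficient. Per the labels, the mice expressed YFP in macrophages and YFP-positive cells were collected by high-speed flow sorting. RNA was purified on microprep columns, about 10 ng was amplified as cDNA with the NuGEN Ovation SPIA system, and the fragmented product carried biotin. The deposited values are log2 expression values as the authors submitted them. The submitters' processing notes name GCOS and RMA, with versions, order and roles not given in the sources used here, nor whether these 4 arrays alone were normalized together. The values were used as deposited, with no further scaling in the main analysis. All 4 arrays were used and no per-sample column was left out. Values ran from 2.75 to 14.9. Array medians were 6.17 (remodeling, Ets2-expressing), 5.98 (remodeling, Ets2-deficient), 6.22 (tumor, Ets2-expressing) and 6.30 (tumor, Ets2-deficient), and Pearson correlations between arrays ran from 0.968 to 0.987.

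Of the 22690 probe sets, 64 were controls, 20380 named exactly 1 gene, 691 several genes and 1619 none. The array annotation was joined to current mouse gene names through Entrez identifiers, which matched 20351 probe sets and updated 0 symbols. Genes were represented by the probe set with the highest mean over the 4 arrays among those naming exactly 1 gene, without controls, which left 12393 genes, 4956 of them with several probe sets. No positions are given, as no genome build is named. The 2246 probe sets not tied to 1 gene were examined apart: 962 were bright in the tumor Ets2 comparison (24 higher and 9 lower past 2-fold) and 966 in the remodeling Ets2 comparison (13 higher and 40 lower).

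With 1 array per group no test was run. Every comparison is a log2 difference per gene, counted where the brighter array lay at or above its median over all probe sets, and called where it was at least 2-fold. The comparisons were Ets2-deficient minus Ets2-expressing in tumor and in remodeling macrophages, tumor minus remodeling for each Ets2 label, and the difference of the 2 Ets2 differences, counted at 1 log2 where at least 1 array was at or above its median. Numbers of shared genes are given beside the number for independent lists, the product of both counts divided by the genes bright in both. Genes are not independent replicates, so correlations across genes are descriptions.

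The spread between bright probe sets of the same gene served as technical error. Among called genes with at least 2 bright probe sets, all bright probe sets lay in the same direction for 27 of 30 genes (tumor Ets2 comparison), 92 of 95 (remodeling Ets2 comparison), 154 of 171 (tumor minus remodeling, Ets2-expressing) and 126 of 130 (tumor minus remodeling, Ets2-deficient). Median standard deviations were 0.219, 0.157, 0.253 and 0.176, and pooled ones 0.335, 0.282, 0.410 and 0.321. The 18 hybridization control probe sets averaged 9.73, 9.53, 9.81 and 9.76 on the arrays in the order given above. The 3' minus 5' differences were 2.72, 2.96, 3.30 and 3.54 for Actb and 1.61, 1.80, 2.45 and 2.27 for Gapdh.

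Gene lists were fixed before the data were examined: macrophage identity, alternative activation and tissue-resident macrophage, classical activation, angiogenesis inhibitors, angiogenesis promoters, extracellular proteases, chemokines and receptors, scavenging and lipid handling, MHC class II, interferon response, cell cycle, immediate early and dissociation stress, hypoxia and glycolysis, ETS family, and markers of fibroblasts, mammary epithelium, adipocytes, endothelium, T and NK cells, B cells, neutrophils, mast cells, dendritic cells, monocytes, and muscle with erythroid cells. The median difference of a list was placed among 10000 random lists of the same size drawn to match mean expression in 20 bins, and called below percentile 2.5 or above 97.5. Such a percentile describes these arrays only. After the data were seen, 6 lists were added: clock genes of the Per, Nr1d and Dbp phase, clock genes of the Arntl phase, eosinophil-associated genes, antibody and plasma cell genes, milk protein genes and epithelial structural genes. Some genes sit in several lists, such as Sparc among both fibroblast genes and angiogenesis inhibitors.

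Genes are named by a rule. It takes the 10 highest and 10 lowest named genes of each pairwise comparison, up to 4 members past 2-fold of each list, 5 highest and 5 lowest of the contrast, and up to 5 shared genes per direction pattern. Ets2, Thbs1, Thbs2, Timp1 and Timp3 are always named. Names outside it were chosen after the data were seen.

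The procedure was tested on simulated data of 12393 genes, built from the mean of each gene over the 4 arrays. The noise, with a standard deviation of 0.219, and the brightness limits were taken from the tumor arrays. It called 1 of 50 genes set to differ 1.5-fold, 47 of 50 set to differ 2.5-fold, and 50 of 50 at 4-fold and at 8-fold. These genes were drawn only from those well above the array median, so recovery of dimmer genes was not tested. Of 6732 unchanged genes 0 were called. Of 1000 lists without a difference 54 were called, and 50 of 50 shifted lists. These lists held random genes with independent noise, so the result does not cover lists of genes that vary together. The shift was added to the list median and was large beside the noise, so those calls were nearly fixed in advance. Recovery of smaller list differences was not tested. The simulated noise was the median spread, below the pooled spread of 0.335, and holds no variation between animals, so the number of unchanged genes called is a lower limit.

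The groups, comparisons, lists, thresholds, naming rule and most alternatives were set before the data were examined. These alternatives were quantile normalization, centring on the array median, cyclic loess (limma), no brightness filter or one at the 75th percentile, the mean of all probe sets of a gene, leaving out probe sets of suffix _x, _s or _a, adding 32 on the linear scale, thresholds of 1.5-fold and 3-fold, and for lists unmatched random lists and bright members only. Centring each array on the mean of its hybridization controls and the sharing of genes between the tumor comparisons were added after the data were seen, as was the count of genes whose dimmer array lay below its 25th percentile. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.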

Results

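Gene expression was measured in macrophages sorted from mouse mammary glands, on 1 array for each of 4 groups. Macrophages came from early-stage mammary tumors driven by the polyoma middle T oncogene (PyMT), a mouse model of breast cancer, or from remodeling glands without tumor. In each setting 1 array was labelled Ets2-expressing and 1 Ets2-deficient. Ets2 encodes a transcription factor of the ETS family. The layout asks which genes differ with Ets2 in tumor macrophages, and whether the same genes differ in remodeling macrophages. The labels name the remodeling control wild type, whereas the tumor control is wild type in its title and carries 1 copy of Ets2 in its source label.

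Array medians on the log2 scale were 6.17 (remodeling, Ets2-expressing), 5.98 (remodeling, Ets2-deficient), 6.22 (tumor, Ets2-expressing) and 6.30 (tumor, Ets2-deficient). Each group had 1 array, so there was no replicate check, no test was run and no p-value is given. The labels give 1 RNA sample per group, and nothing tells how many animals entered each sample. The number of arrays limited the precision. The only error at hand was the spread between probe sets of the same gene, whose standard deviation had a median of 0.219, a pooled value of 0.335 and a 95th percentile of 0.651 in the tumor Ets2 comparison, and 0.157, 0.282 and 0.566 in the remodeling Ets2 comparison. It covers neither animals, sorts nor amplification, and "higher" or "lower" below means higher or lower on these arrays. The 3' minus 5' difference of the Actb control probe sets, larger where RNA is more degraded or amplification shorter, was 2.72, 2.96, 3.30 and 3.54 in the same order of arrays. Between the settings that of Gapdh (1.61, 1.80, 2.45 and 2.27) went with Actb and that of Tfrc (5.75, 5.96, 5.03 and 5.27) ran the other way. Within each setting Actb and Tfrc were larger on the array labelled Ets2-deficient, Gapdh only in remodeling. Where the dimmer array lay below its 25th percentile (4.27, 4.29, 4.32 and 4.29), a difference is against background and its size is not exact. This held for 2 of 216 genes past 2-fold in the tumor Ets2 comparison (Mucl1 and Dmbt1), 23 of 460 in the remodeling Ets2 comparison (Pcolce2, Scara3, Ms4a4b, Glycam1, Zik1, Adm and Plat among them), 24 of 825 in tumor minus remodeling on the Ets2-expressing arrays (with Col9a1, Serpinb2, Gdf10 and Elf5) and 58 of 664 on the arrays labelled Ets2-deficient (with Csn2, Sox10, Ms4a4b and Serpinb2). Sizes are not exact either for genes little above that percentile on the dimmer array. In the tumor Ets2 comparison these included Csn1s1 (4.6), Ecrg4 (4.4) and Wfdc21 (4.9) on the Ets2-expressing array. On the array labelled Ets2-deficient, Inmt (4.7) and Speg (4.9) were among them.

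The Ets2 probe set gave a high signal on every array, including both arrays labelled Ets2-deficient. Its values (1 probe set) were 13.24, 12.97, 12.77 and 12.67 in that order, near the top of each array. The Ets2-deficient minus Ets2-expressing difference was -0.09 in tumor macrophages and -0.28 in remodeling macrophages. The labels do not give the deleted exons, so a probe set outside them would not check the labels. Macrophage identity genes were bright, and by median nearly level, on all 4 arrays, except that Itgam, which encodes the integrin CD11b, lay below the median of every array (5.04, 4.99, 5.99 and 5.26). The median of 21 such genes, among them the colony-stimulating factor receptor Csf1r and the complement gene C1qa, was 11.93, 11.95, 11.93 and 12.02. Their median difference lay between -0.07 and 0.06 in the 4 pairwise comparisons, called in none. Only the fractalkine receptor gene Cx3cr1, at 6.77, 8.99, 9.53 and 10.19, passed 2-fold.

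**Figure D1:**
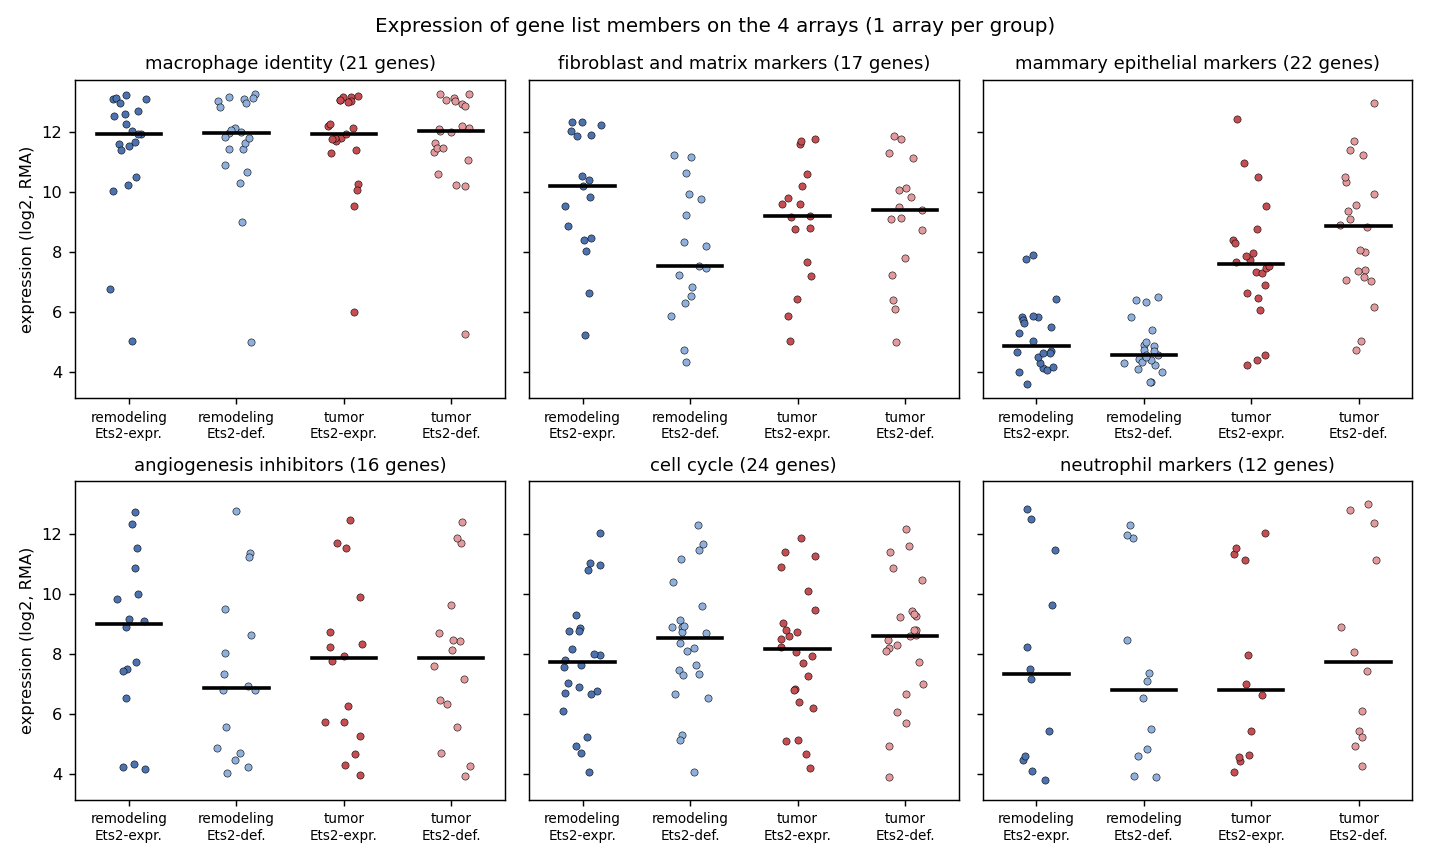
Log2 values of each list member (points) and list medians (bars) on the 4 arrays, 1 panel per gene list. Macrophage identity genes were level (medians 11.93 to 12.02), fibroblast and matrix genes were lowest on the remodeling Ets2-deficient array (7.53 against 10.18 on its control) and mammary epithelial genes were highest on the tumor Ets2-deficient array (8.87).

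In tumor macrophages, milk protein genes and other mammary epithelial genes were higher on the array labelled Ets2-deficient than on the Ets2-expressing array, and so were genes of neutrophils and of the cell cycle. Csn2, which encodes beta-casein, was higher by 3.70 log2, at 11.24 against 7.54. The alpha-casein gene Csn1s1 and the whey acidic protein gene Wap were higher by 3.48 and 2.27 log2. S100a8 and S100a9, calcium-binding proteins abundant in neutrophils, were higher by 1.49 and 1.48 log2. Among the lower genes were the lipid-handling genes Angptl4, whose product inhibits lipoprotein lipase, and Fabp4, a fatty acid carrier, with log2 differences of -1.85 and -1.48.

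Of 7225 genes bright enough to count in this comparison, 161 were at least 2-fold higher and 55 at least 2-fold lower on the array labelled Ets2-deficient. Mucl1, a mucin-like secreted protein, lay at background on the Ets2-expressing tumor array (3.82) and at 8.15 on the other. Next to the caseins and Wap stood Wfdc21 (3.32) and Wfdc12 (2.33), which carry the protease-inhibitor domain of whey acidic protein, the acute-phase gene Saa3 (2.37), the heme-binding protein gene Hebp2 (2.37) and Ecrg4 (2.63). Csn1s2a, another casein gene, was higher by 2.86 and 2.52 log2 in its 2 bright probe sets. On the lower side were Ndufs5, a subunit of mitochondrial complex I (-2.66), the secreted scavenger receptor Dmbt1 (-2.15), the methyltransferase gene Inmt (-1.60), the muscle kinase gene Speg (-1.53), the carbonic anhydrase Car3 (-1.42), the histidine-degrading enzyme Amdhd1 (-1.42), the hematopoietic transcription factor Gata1 (-1.41) and Slc25a53 (-1.40). Higher genes made up 74.5% of those past 2-fold, 58.1% after centring each array on its median, 59.6% after quantile normalization and 82.7% after centring on the hybridization controls.

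Of the 25 gene lists, 4 were called higher and 2 lower in tumor macrophages on the array labelled Ets2-deficient. Among 22 mammary epithelial genes, 21 lay above 0 and 6 were higher past 2-fold (median 0.80, percentile 100 among random lists). Elf5, an ETS factor of the milk-secreting lineage, was 2.32-fold higher. Neutrophil genes had a median of 0.73 with 3 of 12 higher past 2-fold, the chemokine receptor Cxcr2 (1.07) being one. Cell cycle genes were higher by little each: 19 of 24 lay above 0 (median 0.52). Of those bright enough, only Cdc20, an activator of the anaphase-promoting complex, passed 2-fold (1.28). Kif11 differed by 1.42 but was too dim to count (4.65 to 6.07). Hypoxia and glycolysis genes had a median of 0.24 (percentile 98.5). Interferon response genes (median -0.22, percentile 0.875) and B cell genes (-0.38, percentile 0.600) were the lower lists. No gene of these last 3 lists passed 2-fold by the probe set used, but the immunoglobulin gene Ighm, a B cell list member at 0.45, had 4 further probe sets that were dim on the Ets2-expressing tumor array (4.20 to 4.74) and bright on the other (7.06 to 8.38).

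Angiogenesis genes as groups differed little in tumor macrophages. The medians were 0.10 for 16 inhibitors and 0.10 for 19 promoters, neither called. Thbs1, which encodes the antiangiogenic matrix protein thrombospondin-1, was 2.09-fold higher (5.25 to 6.32), and the platelet-derived growth factor gene Pdgfb 2.31-fold. The Thbs1 call lay close to both limits, with its brighter value just above that array's median of 6.30 and a difference of 1.07 log2. Its other probe set, dim on both arrays (3.83 and 4.02), differed by 0.19. Thbs2 (0.19) and the metalloproteinase inhibitor genes Timp1 (0.91) and Timp3 (-0.18) did not pass 2-fold. Also past 2-fold in lists not called were the B cell chemokine Cxcl13 (1.62), the ETS gene Elf4 (1.09), the matrix proteoglycan gene Vcan (1.44) and the collagen-degrading cathepsin gene Ctsk (-1.02). The other medians not called were -0.06 for alternative activation, -0.03 for classical activation, -0.08 for proteases, -0.02 for chemokines, -0.08 for scavenging, 0 for MHC class II, -0.13 for immediate early genes and -0.09 for the ETS family. For cell-type lists they were 0.15 (fibroblast), 0 (adipocyte), -0.10 (endothelial), -0.12 (T and NK cell), -0.24 (mast cell), -0.12 (dendritic cell), 0.16 (monocyte) and 0.02 (muscle and erythroid). Of the 4 adipocyte genes bright enough, 2 (Fabp4 and Car3) were lower past 2-fold, and the median of the 4 was -0.65.

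In remodeling macrophages, genes of fibroblasts and extracellular matrix, inhibitors of angiogenesis, matrix proteases and mast cell genes were lower on the array labelled Ets2-deficient. Cell cycle and B cell genes were higher there. Ptx3, a soluble pattern-recognition protein of innate immunity, had the largest lower difference, -5.77 log2 (10.73 to 4.96). Dcn, which encodes the collagen-binding proteoglycan decorin, and Thbs2, which encodes the antiangiogenic thrombospondin-2, differed by -2.61 and -3.02. The proliferation marker Mki67 was higher by 1.32 log2.

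Of 7095 genes bright enough, 93 were at least 2-fold higher and 367 at least 2-fold lower on the remodeling array labelled Ets2-deficient. The lowest after Ptx3 were the chemokine-scavenging receptor Ackr3 (-4.54), the procollagen-processing enhancer Pcolce2 (-4.49), Islr (-4.43), the scavenger receptor gene Scara3 (-4.11), the serine protease gene Prss23 (-3.60), the phospholipase Pla1a (-3.59), the hexosamine enzyme Gfpt2 (-3.55), the elastin and collagen crosslinking enzyme Loxl1 (-3.46) and Igdcc4 (-3.46). The highest were Ms4a4b, a T cell membrane protein (4.70), the milk mucin Glycam1 (2.71), Cx3cr1 (2.22), the clock activator Arntl (2.20), Gpr155 (2.05), the p53 target Sesn1 (1.76), Zik1 (1.75), the NAD synthesis enzyme Qprt (1.73), the interferon gene Ifnz (1.66) and the mitotic kinase Pbk (1.65). Ms4a4b was bright on the remodeling array labelled Ets2-deficient alone (8.62). Its other probe set, dim on every array, differed by -0.006. Higher genes made up 20.2% of those past 2-fold, 39.5% after median centring and 39.8% after centring on the hybridization controls.

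Fibroblast and matrix genes were lower almost without exception on the remodeling array labelled Ets2-deficient. All 17 measured members lay below 0 and 16 were lower past 2-fold (median -2.08, percentile 0), among them the microfibril gene Mfap5 (-3.03) and the collagens Col5a1 (-2.55) and Col6a1 (-2.31). Of 16 angiogenesis inhibitors, 9 were lower past 2-fold and none higher (median -1.24). They included Timp3 (-3.18), the thrombospondin-motif protease Adamts1 (-2.73), the growth factor signalling inhibitor Spry2 (-1.98), Thbs1 (-1.76) and Timp1 (-1.68). Whether the inhibitor signal came from macrophages or from other cells in the sort was not tested. Angiogenesis promoters had a median of -0.22, with the vasodilator peptide Adm (-2.84) and the growth factor Hbegf (-1.77) past 2-fold. Proteases had 7 of 21 lower past 2-fold (median -0.49), including the plasminogen activator Plat (-3.10), the gelatinase Mmp2 (-2.71) and Htra1 (-2.58). The macrophage elastase Mmp12 was the 1 protease higher past 2-fold (1.16).

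Mast cell proteases were lower as well, and 5 of 9 mast cell genes passed 2-fold (median -1.08), such as Mcpt4 (-3.20), Cma1 (-2.85), Cpa3 (-2.65) and Tpsb2 (-2.36). Mammary epithelial genes had a median of -0.40, with Krt19 (-1.54), Krt18 (-1.51) and the kappa-casein gene Csn3 (-1.27) lower past 2-fold, and Glycam1 higher. Only these 4 of 22 were bright enough, and the list medians lay near background (4.87 on the Ets2-expressing and 4.58 on the Ets2-deficient array). Neutrophil genes (median -0.35) held the decoy interleukin-1 receptor Il1r2 (-1.18) and Cxcr2 (-1.12). By contrast, 23 of 24 cell cycle genes lay above 0 (median 0.66, percentile 100) and 4 were higher past 2-fold, among them the cyclin Ccnb2 (1.31), the mitotic motor Kif11 (1.31) and the survival factor Birc5 (1.11). The other probe sets of Kif11, both dim, gave 0.50 and 0.002. B cell genes were higher in 9 of 9 cases (median 0.92), with the immunoglobulin gene Ighm (1.16) and the CD20 gene Ms4a1 (1.02) past 2-fold. Scavenging and lipid-handling genes were slightly higher (0.17, percentile 98.0, but 93.2 among random lists not matched on expression).

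Called lower by less were classical activation genes (median -0.19, with the inflammatory cytokines Il6 -1.62 and Il1a -1.45), chemokines (-0.15, Ccl17 -2.31 and Cxcl14 -1.88) and hypoxia genes (-0.20, none past 2-fold). Centring on the array median or on the hybridization controls raised every gene of this comparison alike (the median of all genes from 0.04 to 0.23 and 0.24), so these lists and the angiogenesis promoters then had medians near 0, with their place among random lists the same by construction. Lists not called had medians of 0.01 (alternative activation), 0.21 (MHC class II), 0.19 (interferon, with the RNA sensor Oasl1 at -1.36), 0.07 (immediate early), 0.04 (ETS family), 0.18 (adipocyte), -0.04 (endothelial), -0.04 (T and NK cell), 0.14 (dendritic cell), 0.09 (monocyte) and 0.13 (muscle and erythroid). Past 2-fold among them were the endothelial genes Tek (-2.76) and Ramp2 (-2.28) and the monocyte-list gene Vcan (-2.59).

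**Figure D2:**
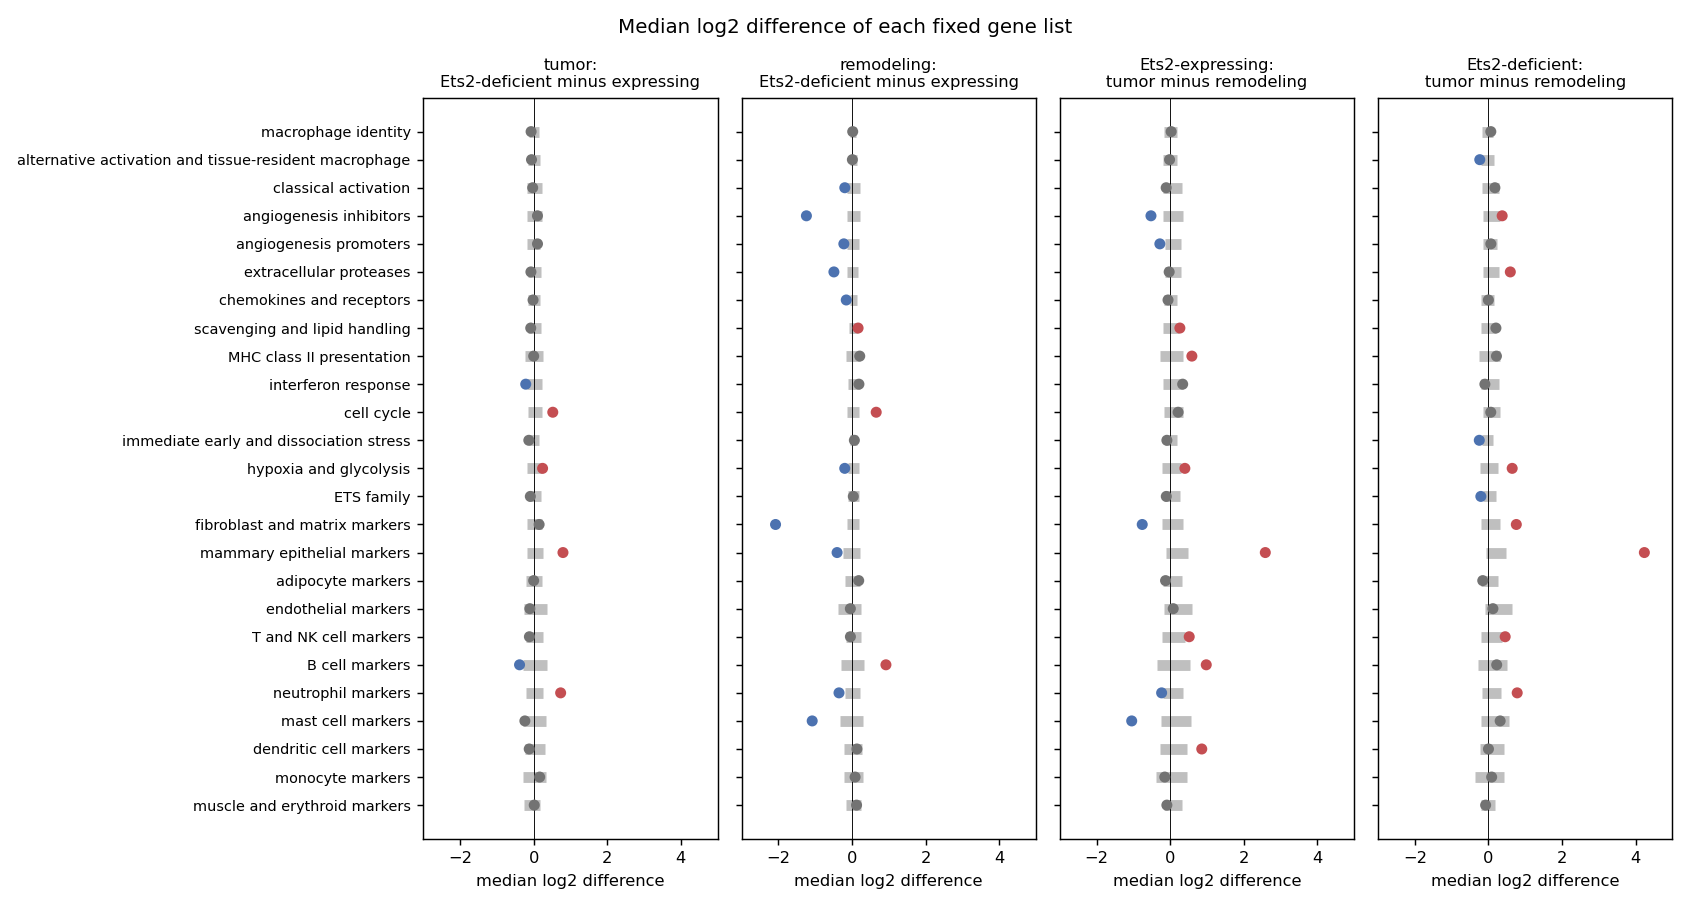
Median log2 difference of each of the 25 gene lists (horizontal axis) in the 4 pairwise comparisons, with the central range of matched random lists in grey and called lists in red (higher) or blue (lower). Fibroblast and matrix genes lay at -2.08 in the remodeling Ets2 comparison and at 0.15 in the tumor Ets2 comparison.

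Few genes were shared by the 2 Ets2 comparisons, some in the same direction and some in opposite directions. The mitotic kinase gene Pbk (1.19 in tumor, 1.65 in remodeling macrophages) and the gap junction gene Gjb2 (1.46 and 1.30) were higher with the Ets2-deficient label in both. Genes lower in both included the clock repressor Per2 (-1.14 and -3.32), Angptl4 (-1.85 and -1.25), the carboxylesterase Ces2g (-1.16 and -3.14), the dipeptidase Dpep1 (-1.16 and -2.54) and the hyaluronan-binding protein gene Itih5 (-1.14 and -2.52). The growth factor gene Tgfb2 (1.62 and -1.85), Vcan and the itaconate-producing enzyme Acod1 (1.21 and -2.37) were higher in tumor but lower in remodeling macrophages. Another Tgfb2 probe set, bright on both tumor arrays, differed by only 0.36 in tumor and by -1.12 in remodeling macrophages. A dim one gave 0.48 and 0.02.

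Of 6849 genes bright in both Ets2 comparisons, 2 were higher past 2-fold in both, where independent lists would share 0.841, and 8 lower in both, where they would share 1.79. In opposite directions lay 15: 13 were higher in tumor and lower in remodeling macrophages (2.86 for independent lists) and 2 the reverse (0.526). Which direction held more genes depended on the processing: the same and opposite directions held 10 and 15 genes here, but 14 and 13 after quantile normalization, 13 and 10 after median centring, 127 and 104 at 1.5-fold and 3 and 2 with the 75th percentile filter. The 2 comparisons share no array. Their controls also differ per the source labels, with 1 copy of Ets2 in tumor and wild type in remodeling. Across the 6849 genes the 2 differences were nearly unrelated (Pearson 0.0648, Spearman 0.10), with the same sign in 52.3%. The difference of the 2 Ets2 differences, a value with no error, was at least 1 log2 higher for 635 genes and lower for 220 of 7473. Its highest genes were Ptx3 (5.40), Csn2 (4.67), Ackr3 (4.52), Mucl1 (4.28) and Pcolce2 (4.15), and its lowest Ms4a4b (-4.66), Ndufs5 (-2.92), Amdhd1 (-2.56), Sec16b (-2.41) and Hoxd9 (-2.27). Of those past this size 74.3% were higher, 43.5% after median centring, 58.0% after centring on the controls and 61.1% after quantile normalization.

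In this contrast the angiogenesis inhibitors and the fibroblast genes were both positive. This largely restates their lower values in the remodeling Ets2 comparison (medians -1.24 and -2.08), as their tumor medians were 0.10 and 0.15. The 4 inhibitors named in advance were positive too: Thbs1 (2.82), Thbs2 (3.21), Timp1 (2.59) and Timp3 (3.00). Their remodeling differences were -1.76, -3.02, -1.68 and -3.18, and their tumor differences 1.07, 0.19, 0.91 and -0.18. The contrast medians were 2.10 for fibroblast and matrix genes, 1.79 for mast cell, 1.38 for mammary epithelial and 1.17 for angiogenesis inhibitor genes. Neutrophil (0.85), protease (0.59), hypoxia (0.59) and angiogenesis promoter genes (0.39) were also positive and called, as were chemokines (0.16, percentile 94.1 among unmatched random lists, and a median of -0.11 after median centring, which shifts all genes of the contrast alike). Negative and called were B cell (-1.02), interferon (-0.42), dendritic cell (-0.40), scavenging (-0.32), immediate early (-0.23, percentile 3.56 unmatched) and macrophage identity genes (-0.18, percentile 2.33, 10.1 unmatched). The macrophage identity median turned to 0.04 without probe sets of suffix _x, _s or _a.

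**Figure D3:**
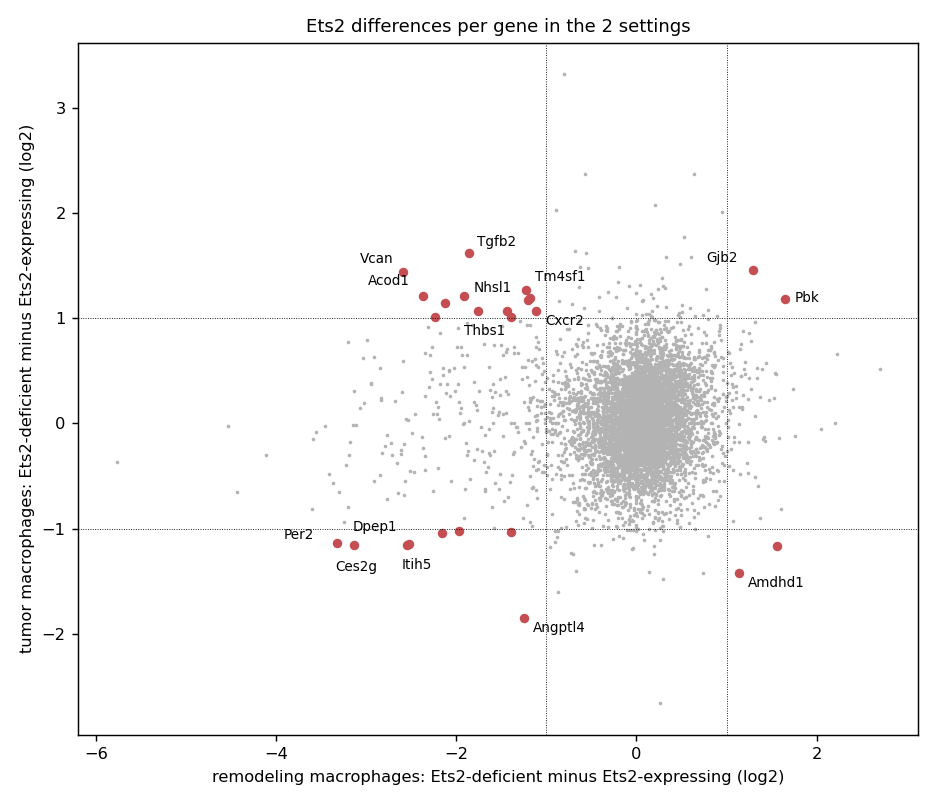
Ets2-deficient minus Ets2-expressing log2 difference in remodeling (horizontal) and tumor macrophages (vertical) for 6849 genes, with dotted lines at 2-fold. The 25 genes past 2-fold in both are in red, 10 in the same and 15 in opposite directions.

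On the Ets2-expressing arrays, genes of mammary epithelium, antigen presentation and B cells were higher in tumor than in remodeling macrophages, and genes of mast cells, fibroblasts and angiogenesis inhibitors lower. Krt8, a keratin of luminal epithelium, was 25.5-fold higher in tumor, at 10.50 against 5.83. Jchain and Igha, which encode parts of secreted antibodies, differed by 6.42 and 5.18. Arg1, the arginine-consuming enzyme typical of tumor-associated macrophages, was higher by 2.46 log2, and Gpnmb, a glycoprotein of lipid-laden macrophages, by 3.64. The clock genes Per2 (-2.72) and Dbp (-2.70) and Thbs1 (-3.84) were lower in tumor.

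Of 7253 genes bright enough, 448 were at least 2-fold higher and 377 at least 2-fold lower in tumor on the Ets2-expressing arrays. The larger side depended on the processing: 54.3% were higher here, but 49.5% after median centring, 48.3% after cyclic loess, 45.7% after centring on the hybridization controls, 48.8% both without probe sets of suffix _x, _s or _a and with 32 added on the linear scale, and 39.4% with the 75th percentile filter. The highest also held the acute-phase genes Saa1 (6.35), Saa2 (4.81) and Lcn2 (4.51), the mucin Muc15 (4.80), Csn3 (4.65), the cartilage collagen gene Col9a1 (4.23) and the epithelial progenitor marker Plet1 (4.21). The lowest after Thbs1 were the plasminogen activator inhibitor Serpinb2 (-3.53), Ptx3 (-3.18), the histone-citrullinating enzyme Padi4 (-3.08), the metalloprotease Adam12 (-2.94), the eotaxin receptor Ccr3 (-2.79), Vcan (-2.78) and the growth factor gene Gdf10 (-2.75). These arrays differ in Ets2 copies per the labels as well as in tumor, and each is also part of an Ets2 comparison above.

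Gene lists called in this comparison numbered 7 higher and 5 lower. Mammary epithelial genes led, with 17 of 22 higher past 2-fold (median 2.58), and with them the ETS genes Elf5 (3.68) and Ehf (2.35). MHC class II genes were higher in 9 of 9 cases (median 0.59, H2-Oa 1.12). B cell (median 0.98, Cd22 2.19 and Cd79a 2.06), T and NK cell (0.52, Cd3g 1.33 and Cd4 1.08) and dendritic cell genes (0.86, the integrin Itgax 1.93 and the transcription factor Batf3 1.08) were higher too. Hypoxia genes had a median of 0.40, with the oxygen sensor Egln3 (1.92) higher and P4ha1 (-1.05) lower past 2-fold. Scavenging genes (median 0.26, percentile 98.5, 93.4 unmatched) included the lipid receptor Trem2 (1.29) and Fabp5 (1.12).

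Lower in tumor on the Ets2-expressing arrays were mast cell genes (median -1.05, 5 of 9 past 2-fold, the histamine-producing enzyme Hdc -1.96), fibroblast and matrix genes (-0.76, 7 of 17, Dcn -2.06 and Dpt -1.84) and angiogenesis inhibitors (-0.52, 5 of 16). Beside Thbs1, the inhibitors past 2-fold included Timp3 (-2.21), Thbs2 (-1.88) and the endostatin precursor Col18a1 (-1.77), whereas Timp1 (-0.29) did not pass. Angiogenesis promoters were lower (-0.28, 4 of 19 past 2-fold), among them the vascular growth factor Vegfa (-1.76), its receptor Flt1 (-1.27) and Hbegf (-1.93). Neutrophil genes were lower by median (-0.23), Il1r2 (-1.67) and S100a9 (-1.31) with them and Lcn2 against them.

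Lists not called on the Ets2-expressing arrays had medians of -0.02 (alternative activation, Lyve1 -1.32), -0.11 (classical activation, Il6 -2.02 and Cd80 -1.22), -0.03 (proteases, the macrophage elastase Mmp12 2.14 and Mmp19 -1.23), -0.06 (chemokines, 3 higher and 4 lower past 2-fold, among them Ccl22 1.18 and the monocyte attractants Ccl7 -2.13 and Ccl2 -1.56), 0.22 (cell cycle), -0.09 (immediate early, Hspa1a -1.07), -0.11 (ETS family, Elf4 -2.24), -0.13 (adipocyte), 0.08 (endothelial, Tek -1.48 and Ramp2 -1.18), -0.15 (monocyte, Plac8 -1.10) and -0.09 (muscle and erythroid). Interferon genes (median 0.34, Irf7 1.23 and Ifit2 1.16) lay at percentile 97.3 and were not called, but lay at 99.0 among unmatched random lists.

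The same comparison on the arrays labelled Ets2-deficient again had mammary epithelial genes higher in tumor, and here fibroblast and matrix genes were higher too. Csn2 lay at background on the remodeling array (3.68) and at 11.24 on the tumor array, with 3.94 and 7.48 in its other probe set, and Krt8 was 63.1-fold higher. Sox9 and Sox10, transcription factors of epithelial and neural crest lineages, differed by 6.12 and 5.65. Their other probe sets, dim on both arrays, gave 0.74 for Sox9 and 0.70 and -0.18 for Sox10. The matrix proteoglycan gene Bgn (3.29) and Timp1 (2.30) were higher in tumor, and the eosinophil genes Rnase2a (-3.20) and Ccr3 (-3.07) lower.

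Of 7203 genes bright enough, 548 were at least 2-fold higher and 116 at least 2-fold lower in tumor on the arrays labelled Ets2-deficient. The highest also held Saa1 (7.04), Csn3 (6.46), Muc15 (6.21), the iron-binding milk protein gene Ltf (5.99), Wap (5.53) and Csn1s2a (5.75). Beside Rnase2a and Ccr3, the lowest were Ms4a4b (-4.55), Ndufs5 (-3.21), Car3 (-2.64), Amdhd1 (-2.47), Serpinb2 (-2.30), the oxidized-lipid receptor Olr1 (-2.23), Lbx1 (-1.93) and Fabp4 (-1.89). Higher genes made up 82.5% of those past 2-fold, 50.8% after median centring, 61.3% after centring on the hybridization controls and 71.5% after quantile normalization.

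On the arrays labelled Ets2-deficient 7 lists were called higher and 3 lower in tumor. Mammary epithelial genes had 18 of 22 higher past 2-fold (median 4.24), with Elf5 (4.77) and Ehf (3.05). Fibroblast and matrix genes had 7 of 17 higher (median 0.76, Col6a2 2.31 and Mfap5 1.91). Neutrophil genes had a median of 0.78 (Lcn2 4.99), but Cxcr2 (0.95), S100a8 (0.94), S100a9 (0.70) and Il1r2 (0.45) did not pass 2-fold. Proteases had a median of 0.59, with 5 higher past 2-fold such as the membrane-bound collagenase Mmp14 (2.31), the stromelysin Mmp3 (2.07) and Mmp2 (1.83). Hypoxia genes were higher (median 0.65), 5 of 16 past 2-fold, including Egln3 (2.72) and the glycolytic enzymes Pfkl (1.78) and Ldha (1.18). T and NK cell genes (median 0.45) split between the cytotoxic granule gene Nkg7 (1.89) and the cytokine receptor Il7r (1.24) on the higher side and Cd28 (-1.55) on the lower. Angiogenesis inhibitors were higher by median (0.37), with Timp1, Spry2 (1.76) and Thbs2 (1.33) higher, Thbs1 (-1.02) lower and Timp3 (0.79) not past 2-fold. Centring each array lowered all genes of this comparison alike, their median from 0.01 to -0.31 with array medians and -0.21 with hybridization controls. The medians then were 0.05 and 0.15 for angiogenesis inhibitors, 0.14 and 0.23 for T and NK cell genes and 0.44 and 0.53 for fibroblast and matrix genes, with the same place among random lists by construction.

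Called lower on these arrays were alternative activation genes (median -0.24, although Arg1 differed by 2.78), immediate early genes (-0.25, none past 2-fold) and the ETS family (-0.21, Spib -1.28 and Elf4 -1.04). Lists not called had medians of 0.18 (classical activation, Il12b 1.84 and Il1a 1.38), 0.07 (angiogenesis promoters, Pdgfb 1.21), -0.002 (chemokines, 4 higher and 2 lower past 2-fold, among them Cxcl14 3.58, Ccl17 2.92, Cxcl13 2.76 and Ccl2 -1.02), 0.20 (scavenging, Gpnmb 2.85 and Cd36 -1.26), 0.22 (MHC class II), -0.10 (interferon), 0.06 (cell cycle), -0.16 (adipocyte), 0.12 (endothelial, Tek 1.17), 0.22 (B cell, Jchain 5.40), 0.32 (mast cell, Cma1 1.13), 0 (dendritic cell, the mucosal integrin Itgae 2.20 and Zbtb46 -1.04), 0.09 (monocyte, Vcan 1.25 and Plac8 -1.07) and -0.08 (muscle and erythroid).

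Part of the tumor differences was shared between the arrays labelled Ets2-expressing and those labelled Ets2-deficient. Epithelial genes such as Csn3, Krt8 and Muc15, the acute-phase gene Saa1 and the antibody gene Jchain were higher in tumor in both, and Ccr3 and Serpinb2 lower in both. Timp1 and Thbs2 were not shared: Thbs2 was lower in tumor on the Ets2-expressing arrays and higher on the deficient ones. Of 6990 genes bright in both comparisons, 202 were higher past 2-fold in both (of 404 on the Ets2-expressing and 452 on the deficient arrays, 26.1 for independent lists) and 43 lower in both (of 289 and 111, 4.59). Fibroblast genes and angiogenesis inhibitors had medians of opposite sign in the 2 comparisons. Opposite directions held 39 genes, 38 of them lower in tumor on the Ets2-expressing arrays and higher on the deficient arrays (18.7) and 1, Sec16b, the reverse (6.42). Across genes the Pearson correlation was 0.580 and the Spearman correlation 0.476, with the same sign in 66.9%. These 2 comparisons share no array with each other, but each shares its arrays with the Ets2 comparisons.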

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

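Every test of an explanation in this part was chosen only after the result was seen.

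Some named genes passed 2-fold in opposite directions in the 2 Ets2 comparisons, which drew attention because Ets2-deficient against Ets2-expressing labels went with opposite array differences. The controls are not alike, however: the tumor control carries 1 copy of Ets2 in its source label, and the remodeling control is wild type. Higher in tumor and lower in remodeling macrophages on the array labelled Ets2-deficient were Tgfb2 (1.62 and -1.85), Vcan (1.44 and -2.59), Tm4sf1, a membrane protein of endothelial and tumor cells (1.27 and -1.23), Nhsl1 (1.22 and -1.91), Acod1 (1.21 and -2.37), Cxcr2 (1.07 and -1.12) and Thbs1 (1.07 and -1.76). Amdhd1 was the reverse (-1.42 and 1.14), as was BC147527, a locus identifier outside the naming rule. In tumor macrophages Thbs1 lay close to both the 2-fold and the brightness limit, and another bright probe set of Tgfb2 differed by only 0.36. The difference between the 2 settings was not tested, since each group had 1 array.

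A few probe sets not tied to exactly 1 gene had large differences, so they stand outside the gene counts. On the arrays labelled Ets2-deficient the highest and lowest such probe sets differed by 4.98 and -1.56 in tumor macrophages, and by 1.64 and -4.81 in remodeling macrophages. Which genes they measure was not resolved here.

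The fibroblast and matrix genes lower on the remodeling array labelled Ets2-deficient may reflect fewer fibroblast transcripts in that sort. Of 17 markers of the list fixed in advance 16 were lower past 2-fold, while the macrophage identity median stayed at 0.02. That count is the pattern itself, so it cannot tell fewer fibroblast transcripts from regulation within macrophages. The YFP sort should remove fibroblasts, yet on the Ets2-expressing remodeling array the most abundant members, Sparc, Col3a1, Col1a1 and Dpt, stood at 12.32, 12.32, 12.22 and 12.02, against 11.22, 10.64, 11.16 and 9.95. A purer sort with every other cell type lower is argued against by the B cell marker median of 0.924. Mast cell, neutrophil and mammary epithelial genes were called lower there as well, while T and NK cell genes were near level (-0.04). Only 4 of 22 mammary epithelial genes were bright enough to count, so that call rests mostly on genes near background. A sort with less of some other cell types therefore stays open. Scaling of the array would move all genes alike. It is argued against by a fibroblast median of -2.08 beside a median of all genes of 0.04 (-1.88 and 0.24 after centring on the hybridization controls). Sparc is also in the angiogenesis inhibitor list, and how many of the 17 markers macrophages themselves express was not measured. Regulation of these genes by Ets2 inside macrophages, or another difference between the animals, stays open and was not tested.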

How the results depend on the processing

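Where a value moved, the cause was not tested unless the setting itself shows it, as with thresholds and brightness filters. A count is said to move where it differed from the main count by more than 1.5 times, and the correlation where it differed by at least 0.1. By this measure 68 values moved, and 95 differed by less. No paired analysis was possible because each group has 1 array and the labels pair no samples across groups. An additive fit of Ets2 label and setting, which would leave 1 residual degree of freedom, was not run. Counts are given in a fixed order: tumor Ets2 comparison higher and lower, remodeling Ets2 comparison higher and lower, tumor minus remodeling on the Ets2-expressing arrays higher and lower, the same on the arrays labelled Ets2-deficient, the contrast of the Ets2 differences higher and lower, genes shared by the Ets2 comparisons in the same and opposite directions, and genes shared by the tumor comparisons in the same and opposite directions. In the main analysis they were 161, 55, 93, 367, 448, 377, 548, 116, 635, 220, 10, 15, 245 and 39.

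With a 1.5-fold threshold these counts became 670, 433, 463, 690, 1223, 942, 1145, 559, 1219, 879, 127, 104, 691 and 111. A 3-fold threshold left 37, 4, 11, 220, 172, 145, 327, 22, 316, 33, 0, 1 (Tgfb2), 132 and 8. Requiring the brighter array to reach its 75th percentile left 49, 13, 21, 130, 110, 169, 154, 56, 220, 61, 3, 2, 72 and 7. The 5 genes shared by the Ets2 comparisons were then Angptl4, Dpep1, Itih5, Igfbp7 and Tgfb2, of which Igfbp7 falls outside the naming rule. Without a brightness filter the tumor Ets2 comparison had 102 lower genes, 19 and 29 genes were shared by the Ets2 comparisons in the same and opposite directions, and 59 were shared by the tumor comparisons in opposite directions.

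Adding 32 on the linear scale gave 87 higher and 13 lower genes in the tumor Ets2 comparison and 37 higher genes in the remodeling Ets2 comparison. It gave 269 higher genes in tumor on the Ets2-expressing arrays, 77 lower genes on the arrays labelled Ets2-deficient and 102 lower genes in the contrast. Shared genes numbered 4 in the same and 5 in opposite directions for the Ets2 comparisons, and 24 in opposite directions for the tumor comparisons. Taking the mean of all probe sets of a gene left 36 lower genes in the tumor Ets2 comparison, 73 lower genes in tumor on the arrays labelled Ets2-deficient, and 8 genes in opposite directions in the Ets2 comparisons.

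Median centring gave 91 lower genes in the tumor Ets2 comparison, 192 higher genes in the remodeling Ets2 comparison, 382 lower genes in tumor on the arrays labelled Ets2-deficient and 557 lower genes in the contrast. Quantile normalization gave 97, 183 and 332 lower genes in the tumor Ets2 comparison, in tumor on the arrays labelled Ets2-deficient and in the contrast. Centring on the hybridization controls gave 194 higher genes in the remodeling Ets2 comparison, 272 lower genes in tumor on the arrays labelled Ets2-deficient and 366 lower genes in the contrast. Cyclic loess moved no count by more than 1.5 times, although tumor minus remodeling on the Ets2-expressing arrays had 392 higher and 419 lower genes, so that the larger side turned, as it did after median centring (405 and 414) and after centring on the controls (375 and 445). Genes shared by the Ets2 comparisons in the same and opposite directions numbered 14 and 13 after quantile normalization and 13 and 10 after median centring, which turned their order. The median of all genes was 0.04 in the remodeling Ets2 comparison in the main analysis, 0.23 after median centring and 0.24 after centring on the controls. For tumor minus remodeling on the arrays labelled Ets2-deficient it was 0.01, -0.31 and -0.21.

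Of the list medians 230 values moved by more than the median spread between probe sets, 6 turned direction and 996 did neither. Of the named genes' differences 594 values moved by this measure, 2 turned direction and 1800 did neither. Named genes moved most often with 32 added (155 values), with either centring (141 each) and with the mean of all probe sets (95). Either centring shifts all genes of a comparison by the same amount, so it cannot change the place of a list among random lists, and 5 of the 6 turns of list medians are of this kind. In the remodeling Ets2 comparison chemokines turned to 0.0395 after median centring and 0.0455 after centring on the controls, and with the latter classical activation turned to 0.0055 and hypoxia to 0.004. In the contrast chemokines turned to -0.113 after median centring and macrophage identity to 0.04 without probe sets of suffix _x, _s or _a. Without those probe sets Csn1s2a gave -0.334 in the tumor Ets2 comparison and -0.319 in tumor minus remodeling on the arrays labelled Ets2-deficient, from a probe set at background (3.94, 3.95 and 3.62 on these arrays), which says nothing about the gene. With unmatched random lists 5 called lists were no longer past the limits: macrophage identity (percentile 10.1), chemokines (94.1) and immediate early genes (3.56) in the contrast, and scavenging in the remodeling Ets2 comparison (93.2) and in tumor minus remodeling on the Ets2-expressing arrays (93.4). Interferon genes passed in the last of these comparisons (99.0).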

Other observations

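The tests of explanations in this part, and the lists of eosinophil-associated, antibody, milk protein, epithelial structural and clock genes, were chosen only after the results were seen, and the bounds of the milk protein and clock gene tests were revised after the values of these tests were known.

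Eosinophil-associated genes were lower in tumor than in remodeling macrophages with either Ets2 label. Siglecf, a sialic acid receptor of eosinophils and some macrophages, stood at 10.17, 9.90, 8.35 and 8.25 on the remodeling Ets2-expressing, remodeling Ets2-deficient, tumor Ets2-expressing and tumor Ets2-deficient arrays, and the ribonuclease Rnase2a at 11.78, 11.98, 10.02 and 8.78. The eotaxin receptor Ccr3 was at 7.91, 8.35, 5.13 and 5.28, the interleukin-5 receptor Il5ra at 6.39, 6.30, 4.96 and 4.85 and the lipoxygenase Alox15 at 9.39, 8.88, 8.09 and 7.70. Of 8 genes 5 and 6 were lower past 2-fold in the 2 tumor comparisons (medians -1.36 and -1.55). In the tumor Ets2 comparison the median was -0.11, but 7 of 8 lay below 0, and Rnase2a (-1.24) and Gata1 (-1.41) were lower past 2-fold on the array labelled Ets2-deficient (median of the bright members -0.81). The remodeling Ets2 comparison had a median of 0.11 and no member past 2-fold.

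The antibody genes Igha and Jchain were far higher in tumor, whereas 2 regulators of plasma cell identity were not past 2-fold. In log2 values, Igha stood at 6.70, 6.82, 11.87 and 12.08 and Jchain at 4.31, 5.35, 10.73 and 10.76 in the same order of arrays, while the plasma cell regulators Prdm1 (7.91, 7.07, 7.17 and 6.68) and Xbp1 (10.34, 10.09, 10.47 and 10.56) were not past 2-fold in any comparison. Both regulators were already expressed on the remodeling arrays, where Jchain was dim, so they do not tell whether plasma cells contributed. The list of 7 antibody and plasma cell genes was called in no comparison, with medians of 0.03 and -0.04 in the tumor and remodeling Ets2 comparisons and 0.17 and 0.47 in tumor minus remodeling on the Ets2-expressing and Ets2-deficient arrays.

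Milk protein genes were higher on the tumor array labelled Ets2-deficient, with a median of 2.27 against 0.45 for epithelial structural genes. A larger share of epithelial cells in that sort may be part of this and was not excluded: 4 of 7 milk protein genes lay above the highest of 11 structural genes (0.947) by more than the spread between probe sets, but all 4 were among the genes that drew attention, and 0 of the other 3 did (Csn3 0.54, Lalba 1.06 and Glycam1 0.52). Compression of differences at the ends of the scale stays open in the same way, with 3 of 5 milk protein genes above that bound among genes between 6 and 9 on the Ets2-expressing tumor array. The milk and structural medians among those genes were 2.27 and 0.37, no closer than over all members. However, the 3 genes were again among those that drew attention. The most abundant milk genes, Csn3 and Csn2, stood at 12.96 and 11.24, and the structural genes Krt18 and Krt8 at 11.71 and 11.39, although the YFP sort should remove epithelial cells, and both lists lie within the mammary epithelial list. A different state of the epithelium or of the animals was not tested.

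In the other comparisons the milk and structural medians were -0.32 and -0.65 (remodeling Ets2 comparison), 3.03 and 2.48 (tumor minus remodeling, Ets2-expressing) and 5.53 and 3.08 (Ets2-deficient).

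Clock genes set the remodeling Ets2-expressing array apart from the other 3, with Per2 at 9.09, 5.77, 6.37 and 5.23, Dbp at 11.43, 8.77, 8.73 and 8.35, Arntl at 5.76, 7.96, 7.21 and 7.21 and Npas2 at 5.07, 6.41, 7.07 and 6.47. Collection of that tissue at another phase of the day may be a reason, but the values point both ways: 7 of 7 genes of the Per, Nr1d and Dbp phase other than Per2 and Dbp were highest on that array (Hlf by little, 5.26 against 5.19 on the tumor array labelled Ets2-deficient), whereas 0 of 3 genes of the Arntl phase other than Arntl and Npas2 were lowest on it. Loss of Ets2 alone would put the Per, Nr1d and Dbp phase genes of the Ets2-expressing tumor array above those of the remodeling array labelled Ets2-deficient. Their median difference was only 0.143, against 1.68 for the Ets2-expressing remodeling array, which goes against this explanation. Loss of Ets2 still stays open, because the arrays of the 0.143 value also differ in tumor. The tumor Ets2 comparison also called the same list lower (-0.38, percentile 0.835, 8 of 9 below 0). More fibroblast transcripts on the remodeling Ets2-expressing array cannot be told apart either, as the same arrays differ in tumor. Fibroblast markers of the Ets2-expressing tumor array lay 1.12 above the remodeling array labelled Ets2-deficient, while the clock genes did not follow. The labels give no collection time.

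The Per, Nr1d and Dbp phase genes had medians of -0.38 and -1.68 in the tumor and remodeling Ets2 comparisons and -1.79 and -0.38 in tumor minus remodeling on the Ets2-expressing and Ets2-deficient arrays. Genes of the Arntl phase had 0, -0.10, -0.64 and -0.24 in the same order. The latter list was called lower in tumor minus remodeling on the Ets2-expressing arrays (percentile 1.62), with 3 of 5 below 0. None of these 3 passed 2-fold, while Arntl (1.45) and Npas2 were higher past 2-fold, and the mean of the list was 0.26.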
